A study of Mus musculus with 38 samples.

How the data were processed

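RNA from the uninjected 4th mammary fat pad of 38 tumour-bearing female mice was measured by sequencing of poly-A selected, non-directional libraries with paired reads of 150 bases. The labels put 8 mice each in the lean, obese, operated and restricted groups and 6 in the diet switch group, and give each library its own animal. Replicates were numbered in the order of the records, which pairs no mice between groups.

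For each mouse the authors deposited 1 table of 142699 transcripts with estimated counts, which are unnormalised numbers of reads assigned to each transcript by a quantification program whose name, version and annotation release the notes do not give. The deposited tables also hold TPM values, made by the authors' program from these counts by division by effective length and scaling within each library; TPM values were not used here. The notes name the mouse genome build GRCm38, edgeR and limma, without their versions or roles. In transcripts over 600 bases the effective length was the length minus 250 bases in the library where this was computed, restricted mouse 8. That file carries no length distribution of its own.

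Transcripts were matched by identifier to the GENCODE M21 annotation of GRCm38, and 141469 matched. Their estimated counts were summed over 55260 genes and rounded. The unmatched transcripts, which were left out, held between 0.323% and 0.81% of the counts of a library. Sums over transcripts cannot separate genes with near-identical copies, and in non-directional libraries they cannot separate genes that overlap on opposite strands. The precision of a count is limited by counting error and by the variation between mice, which the SD of each group includes.

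Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test, with TMM normalisation, the default filter by group (a count of 10 and a total of 15) and all 5 groups in 1 fit, two-sided, with Benjamini-Hochberg adjustment over the 21204 genes of a comparison and a threshold of 0.05. There were 9 comparisons: each treated group with obese mice, obese with lean mice, operated with restricted and with switched mice, and each treated group with lean mice. Restricted and switched mice were not compared. Every adjusted p of a gene comes from this edgeR fit or from the same fit without the mouse named. Standard errors are the size of the log2 fold change divided by the square root of its F statistic. CPM values use TMM library sizes.

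In each comparison 45 gene lists fixed before the data were examined were tested with camera (limma 3.58.1, preset correlation 0.01), with camera and an estimated correlation, and with fry. After the data had been seen, a further test was added: the mean log2 CPM of each list in each mouse was permuted between the groups over all arrangements, two-sided, with adjustment over the 45 lists of the comparison. It was repeated without each mouse in turn and without the libraries with visceral fat transcripts. These are the exact permutation p values of list means, and the smallest they can give is 0.000155 for 8 against 8 mice.

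The genes named were to be the 10 with the highest and the 10 with the lowest fold changes among those past the threshold with an average log2 CPM of at least 1 and a symbol that is not a clone name, up to 4 members of each list that was called or had 3 or more members past the test, and 6 fixed genes beside their lists. Where fewer than 5 genes passed, the 5 with the smallest p were to be given as values. That rule named 371 genes in 810 pairs of gene and comparison. The text gives 89 genes in 175 pairs, which were picked from these after their values had been seen.

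The alternatives set before the data were examined were RLE size factors, no filter on low counts, an offset for transcript length, the series of animal numbers as a term, tissue composition covariates, fits of 2 groups alone, limma-voom, DESeq2 1.42.0, a further threshold of 1 on the log2 scale, and leaving out each library in turn. Chosen after the data had been seen were fits without libraries rich in lymphoid transcripts (B cell list mean above 2 log2 CPM), in muscle transcripts (muscle list mean above 2) or in transcripts of visceral fat (list mean above 0), fits without 2 diet switch libraries in which few transcripts had counts (38638 and 38324), and fits within a number series. For genes that moved back after treatment, unchanged groups were simulated 20 times by redrawing every group. For each comparison 30 divisions of the mice were refitted.

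The procedure was tested on simulated data with 215 changed genes. It recovered 47.8% of those changed by 1 and 90% of those changed by 2 on the log2 scale, and 5.23% of its 153 calls were false. Of 20 random lists camera called 0. The simulation drew each gene on its own, so its lists held no correlation between genes. It therefore does not test camera on lists whose genes vary together, such as T cell genes (estimated correlation 0.94). Copied libraries were looked for in 127 pairs within groups, where the log2 CPM correlation across genes, which are not independent replicates, ran from 0.821 to 0.974, and none were found. No library was left out of the main results.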

Results

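The data set held RNA sequencing of the fourth mammary fat pad from 38 female C57BL/6J mice, each library from a separate mouse. The pad was the one opposite an E0771 tumour, a mouse breast cancer cell line implanted in the other side. The mice fell into 5 groups. Lean mice stayed on a low-fat diet (LFD, 8 mice), with 10% of energy from fat, and obese mice stayed on a high-fat diet (HFD, 8 mice), with 60% of energy from fat. The other 3 groups were obese first and then lost weight: by vertical sleeve gastrectomy, an operation that removes most of the stomach (VSG, 8 mice), by caloric restriction matched to the weight of the operated mice (CR, 8 mice), or by a switch to the low-fat diet (DS, 6 mice). All mice outside the VSG group had a sham operation, and the labels do not state the diet given during restriction beyond the high-fat diet. The libraries held between 54703132 and 78280654 estimated read counts each, and 21204 genes were tested. Levels are given as CPM, counts scaled to a common library size (mean ± SD over the mice of a group), and differences as log2 fold changes ± SE. The animal numbers in the sample titles form 3 series, and the counts of genes within a series stand beside the pooled ones. The series were not balanced over the lean, obese, operated, restricted and switched groups. In that order series 1 held 2, 4, 3, 2 and 1 mice and series 2 held 4, 3, 5, 4 and 3. Series 3 held 2, 1, 0, 2 and 2.

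Obese and lean mice also differed in their food, so their comparison does not separate obesity from the high-fat diet. Genes for making fat from sugar were lower in obese mice and genes of adipocyte hormones, matrix, complement and macrophages were higher. Lep, which encodes the satiety hormone leptin (chromosome 6, 29060220 to 29073877, GRCm38), stood at 2776 ± 1213 CPM in obese and 259 ± 191 CPM in lean mice (n = 8 each), a log2 fold change of 3.42 ± 0.54 (adjusted p = 5.56e-05). Elovl6, a fatty acid elongase (chromosome 3, 129532355 to 129638495), stood at 17.6 ± 7.88 against 750 ± 452 CPM (log2 fold change -5.41 ± 0.57, adjusted p = 2.42e-07). For both genes all 8 obese mice lay beyond the lean median. In all, 1403 genes were higher and 990 lower in obese mice, and 1151 of the 2393 also differed by more than 1 on the log2 scale.

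Of the 16 measured genes of de novo lipogenesis, 8 fell and none rose in obese mice (11 fell when adjusted over the list alone). Besides Elovl6 these included Acaca, the first committed enzyme of fatty acid synthesis (log2 fold change -3.46 ± 0.49), Acly, which supplies cytosolic acetyl-CoA (-3.12 ± 0.46), and Thrsp, a lipogenic regulator (-3.20 ± 0.57). The fructose transporter Slc2a5 fell from 27.4 ± 18.3 to 0.0731 ± 0.0692 CPM. The mean of the list per mouse was lower in obese mice (exact permutation p = 0.000155, adjusted over 45 lists 0.00175). Of 15 adipokine and obesity marker genes, 7 rose and none fell (9 rose and 2 fell adjusted over the list alone). Mest, a marker of adipocyte enlargement, rose by 5.53 ± 0.82, Sfrp5, a secreted Wnt inhibitor, by 5.08 ± 0.79, and Npr3, the natriuretic peptide clearance receptor, by 2.87 ± 0.49. The list mean per mouse had an exact permutation p of 0.000155. Adipoq, which encodes adiponectin, did not pass the test (log2 fold change 0.72 ± 0.33, adjusted p = 0.161). Abat, which breaks down the transmitter GABA, rose by 3.97 ± 0.50.

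Some matrix, complement and macrophage genes rose with these. Of 18 fibrosis and matrix genes, 8 rose and none fell (10 rose adjusted over the list alone), with Sparc at 4236 ± 1807 against 1201 ± 263 CPM, Thbs2 (log2 fold change 2.63 ± 0.53) and Col6a1 (1.83 ± 0.36) among them. Of 12 complement genes, 6 rose and none fell (10 rose and 1 fell adjusted over the list alone), including Serping1 (2.09 ± 0.25), C4b (1.95 ± 0.30) and C6 (3.55 ± 0.69). Of 14 macrophage genes, 3 rose (9 adjusted over the list alone), among them Mrc1 (1.00 ± 0.28) and Csf1r (0.80 ± 0.26). In the list of lipid-associated macrophages, 2 of 13 genes rose and 1 fell (6 and 1 adjusted over the list alone). Trem2, a lipid receptor of such macrophages, rose by 2.26 ± 0.74, and Itgax had a log2 fold change of 1.16 ± 0.49 (adjusted p = 0.126). Itgad, an integrin subunit of macrophages, rose from 0.323 ± 0.517 to 18.3 ± 19.8 CPM. The list means per mouse had exact permutation p values of 0.00746 for matrix, 0.000155 for complement, 0.000777 for macrophages and 0.0172 for lipid-associated macrophages, which are 0.0305, 0.00175, 0.00699 and 0.0554 after adjustment.

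Respiratory, epithelial and hormone-response genes were lower. Of 16 nuclear genes of oxidative phosphorylation 7 fell and none rose (15 fell adjusted over the list alone), with Cox5a at -0.96 ± 0.19 and Cox6c at -0.81 ± 0.21 on the log2 scale. Of 13 mitochondrially encoded transcripts 6 fell (12 adjusted over the list alone), such as mt-Atp8 (-1.27 ± 0.31). Of 10 brown adipocyte genes 3 fell (5 adjusted over the list alone), including Cidea (-2.85 ± 0.81) and Elovl3 (-3.61 ± 0.99). Of 18 mammary epithelial genes 3 fell (14 adjusted over the list alone), namely the keratin gene Krt19 (-2.33 ± 0.69), the prolactin receptor gene Prlr (-2.20 ± 0.66) and Spint2 (-1.39 ± 0.41). Of 9 genes that respond to oestrogen or progesterone 3 fell and 1 rose: Areg (-3.64 ± 0.88), Pgr (-2.43 ± 0.71) and Wnt4 (-2.26 ± 0.65) fell. The exact permutation p of the list mean per mouse was 0.00513 for oxidative phosphorylation, 0.00311 for mitochondrial transcripts, 0.00435 for brown adipocytes, 0.00357 for epithelium and 0.000155 for hormone response. Of the obese libraries 3 also carried transcripts typical of visceral fat, of which 2 had epithelial means of -1.53 and -1.75 log2 CPM.

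With its preset correlation camera called 15 lists, with an adjusted p of 3.03e-10 for lipogenesis, 5.4e-06 for adipokines, 3.93e-06 for complement, 2.06e-12 for epithelium and 0.0533 and 0.051 for lipid-associated macrophages and hormone response, which were not called. With an estimated correlation none was called, and the adjusted p lay between 0.412 and 0.68 for the lists named here. Leaving out 1 mouse ended the call of Trem2 in 10 of 16 fits (adjusted p up to 0.0965), of Csf1r in 7 (0.097), of Spint2 in 4 (0.0721), of Prlr in 3 (0.0532) and of Krt19 in 1 (0.0528). Without the libraries with visceral fat transcripts, which left 5 obese mice, the list mean of lipid-associated macrophages differed by 0.59 (exact permutation p = 0.113) that of epithelium by -2.05 and that of matrix by 0.70 (exact permutation p = 0.0202, adjusted 0.0649, for each of the last pair). The count of genes was 18 within number series 1 and 346 within series 2, and series 3 held a single obese mouse. It was 1158 without the 8 libraries rich in muscle transcripts and 1493 without the 4 with visceral fat transcripts.

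**Figure D1:**
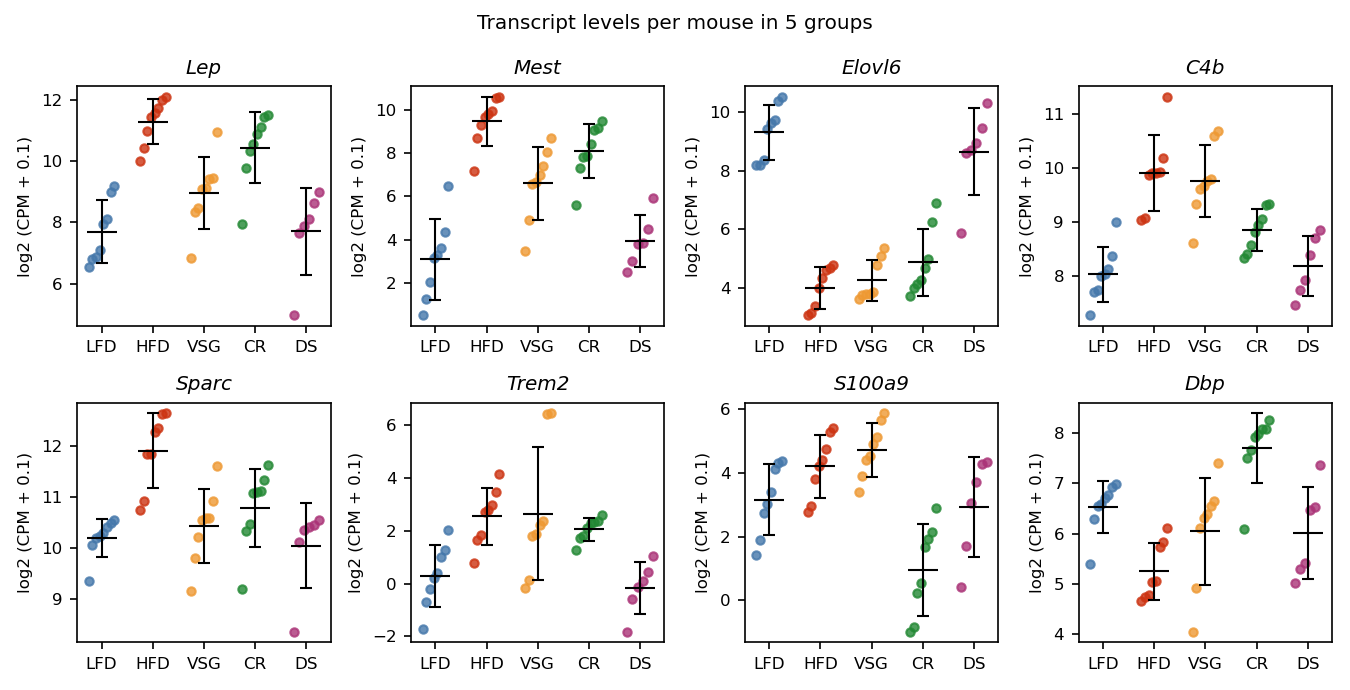
Levels of 8 genes in each mouse (points) of the 5 groups, as log2 of CPM plus 0.1, with the group mean (bar) and SD (whiskers). Mean Elovl6 was at most 39.9 CPM in obese, operated and restricted mice and 750 CPM in lean mice.

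Switched mice, which had changed to low-fat food and lost weight, were compared with obese mice to follow these differences. The comparison does not separate the food from the weight. Relative to obese mice, switched mice had 694 genes higher and 1013 lower. Lipogenic genes rose: Elovl6 by 4.97 ± 0.57, Acly by 3.38 ± 0.48, Acaca by 3.33 ± 0.51 and Fasn, the fatty acid synthase gene, by 3.95 ± 0.75, to 11563 ± 7419 CPM (n = 6). Of the 16 lipogenic genes 7 rose and none fell (8 rose adjusted over the list alone), and Slc2a5 rose by 8.34 ± 1.04. Adipokine genes fell in 6 of 15 cases, with none rising (7 fell and 1 rose adjusted over the list alone). Lep fell to 275 ± 165 CPM (log2 fold change -3.33 ± 0.61), Mest to 20.9 ± 20.7 CPM (-5.37 ± 0.93) and Sfrp5 to 14.9 ± 12.4 CPM (-5.15 ± 0.90). In all 6 switched mice these 3 genes lay below the obese median.

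Some complement and matrix genes fell as well. Of 12 complement genes 4 fell (5 adjusted over the list alone), among them Serping1 (-1.87 ± 0.28) and C4b (-1.80 ± 0.33), and of 18 matrix genes 5 fell (11 adjusted over the list alone), such as Sparc (-1.86 ± 0.37) and Thbs2 (-2.69 ± 0.59). Of 13 genes of lipid-associated macrophages 3 fell (4 adjusted over the list alone): Trem2 (-2.90 ± 0.85), Atp6v0d2 (-3.28 ± 0.93) and Mmp12 (-3.29 ± 1.00). Itgax had a log2 fold change of -0.63 ± 0.53 (adjusted p = 0.479) and Adipoq of -0.77 ± 0.36 (adjusted p = 0.178). Of 13 mitochondrially encoded transcripts 9 rose (13 adjusted over the list alone), mt-Atp8 by 1.64 ± 0.33 and mt-Cytb by 1.43 ± 0.33, and of 16 oxidative phosphorylation genes 4 rose (9 adjusted over the list alone), with Cox5a at 0.90 ± 0.20. The exact permutation p of the list mean per mouse was 0.000333 for adipokines, 0.00233 for complement, 0.011 for lipogenesis, 0.019 for matrix, 0.00733 for lipid-associated macrophages, 0.00899 for mitochondrial transcripts and 0.0426 for oxidative phosphorylation. Over 45 lists the adjusted values were 0.015, 0.035, 0.0792, 0.0982, 0.0792, 0.0792 and 0.16. Switched mouse 5 was lowest of its group in matrix (4.54 against 6.07 to 6.65 log2 CPM) and lipid-associated macrophages (4.29 against 5.09 to 5.42). It was also lowest in adipokines (3.42 against 5.24 to 5.72) and, against the direction of the group, in lipogenesis (6.73 against 8.91 to 9.99). This library was rich in lymphoid transcripts (B cell list mean 7.40 log2 CPM). Its adipocyte list mean was 7.43, against 10.01 to 10.15 in the other switched mice. The low values of this mouse thus cannot be told apart from its tissue make-up. Without the obese libraries with visceral fat transcripts adipokines and complement had adjusted values of 0.0974 each, with differences of -1.75 against -1.86 and -0.95 against -0.97 with all mice. Camera called each of these 7 lists with its preset correlation (adjusted p from 8.71e-10 to 0.046) and none with an estimated correlation (adjusted p 0.691 or 0.722). Leaving out 1 mouse ended the call of Mmp12 in 8 of 14 fits (adjusted p up to 0.0732), of Trem2 in 5 (0.0752), of Atp6v0d2 in 2 (0.065) and of mt-Cytb in 1 (0.0666). The count of genes was 140 within series 2, and 515 without switched mice 5 and 6, which had the highest shares of mitochondrial transcripts (15.2% and 24.2%). Mice 5 and 6 were also the switched mice of number series 3. The fit without mouse 6 of the switched group gave 997 genes, and the fit without mouse 4 of the obese group 1088.

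Between switched and lean mice edgeR called 0 genes, with 657 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 18. Lep differed by 0.09 ± 0.53 and Elovl6 by -0.44 ± 0.51 on the log2 scale. The 5 genes with the smallest p values were Ccdc152 (log2 fold change 2.27 ± 0.46), Krt77 (-7.38 ± 1.76), Krtdap, which was listed at 0 in the switched mice, at least 184-fold lower with a floor of 3 counts over the group, Gm38431 (1.46 ± 0.36) and G6pc (5.55 ± 1.36). None passed (adjusted p from 0.419 to 0.819). Camera called 14 lists and none with an estimated correlation, and none of 45 list means per mouse passed (smallest adjusted exact permutation p = 0.3). Krt77 and Krtdap were highest in lean mouse 7, at 56.1 and 11.5 CPM, against group means of 7.67 and 1.61 CPM that include it. The list of keratinocyte genes, which mark skin, had a mean of 4.38 log2 CPM in that mouse, -1.55 to -0.04 in the other lean mice and -2.50 to -1.04 in the switched ones. Its mean differed by -1.76 (exact permutation p = 0.0147, adjusted 0.32), and by -1.97 to -1.12 when any 1 mouse was left out (exact permutation p up to 0.0466).

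The comparison of operated with obese mice, both on the high-fat diet, gave the difference after surgery. Lep fell from 2776 ± 1213 to 654 ± 565 CPM (log2 fold change -2.09 ± 0.51, adjusted p = 0.04) and Sparc to 1533 ± 771 CPM (-1.47 ± 0.33, adjusted p = 0.0317), each below the obese median in 8 of 8 operated mice. Mrc2, a collagen receptor gene, fell by 2.16 ± 0.39, the vascular peptide gene Apln by 2.17 ± 0.39, and Hmgcs1, of sterol synthesis, by 1.26 ± 0.31. Itgad fell by 5.10 ± 1.17 and Tfr2, a transferrin receptor gene, by 3.33 ± 0.71. Genes that rose included Slc7a2, a transporter of basic amino acids (2.40 ± 0.58), Piezo2, a mechanosensitive channel gene (2.75 ± 0.63), Prom1 (2.21 ± 0.52) and Clec10a, a macrophage lectin gene (1.07 ± 0.27). Elovl6 stood at 21.3 ± 11.3 CPM in operated and 17.6 ± 7.88 CPM in obese mice and did not pass the test. In all 56 genes were higher and 102 lower.

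In the adipokine list 2 of 15 genes fell (6 adjusted over the list alone), and the list mean per mouse was lower by 1.10 on the log2 scale (exact permutation p = 0.0014, adjusted 0.0629), while Adipoq had a log2 fold change of -0.85 ± 0.33 (adjusted p = 0.159). Of 18 mammary epithelial genes none passed over all genes and 12 rose adjusted over the list alone (median log2 change 1.83, exact permutation p of the list mean = 0.0618). Of the libraries with visceral fat transcripts 3 were obese and 1 operated, and the epithelial means of obese mice 1 and 3 were -1.53 and -1.75 log2 CPM. Of 15 T cell genes none passed. Cd8a, of cytotoxic T cells, had a log2 fold change of 2.12 ± 1.68 (adjusted p = 0.503). The T cell list had a median log2 change of 2.02 and an exact permutation p of 0.107 for its mean, and lymphoid-rich libraries numbered 3 in the operated and 1 in the obese group. Skeletal muscle transcripts had a median log2 change of -4.38, with Myh2 at 0.216 ± 0.0981 against 38.8 ± 97.8 CPM, and muscle-rich libraries numbered 1 and 3. Igha, an antibody heavy chain gene of a family with near-identical members, stood at 109 ± 266 CPM after surgery, of which operated mouse 1 alone held 767 CPM; the call was lost without that mouse (log2 fold change 1.31, adjusted p = 0.164).

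Camera called 18 lists in this comparison, among them epithelium (adjusted p = 6.36e-11), adipokines (0.000103), T cells (0.00857) and skeletal muscle (0.0125), and none with an estimated correlation (adjusted p 0.71 for each list named here). The count of 158 genes did not hold up across settings: it was 0 in a fit of the 2 groups alone, 0 with composition covariates, 37 with the number series as a term and 1285 with DESeq2, and 0 within number series 1 and within series 2. The covariates were the list means of mammary epithelium, B cells and skeletal muscle in each library. The epithelial mean was 2.47 in obese and 5.27 in operated mice, so that fit may also take out part of the group difference. None of the 13 called genes named here kept its call under every alternative set before the data were examined, or without each library in turn. Clec10a lost its call in 12 of 16 fits without 1 mouse and Lep in 11 (adjusted p up to 0.152 and 0.12), and the count ran from 0 to 873 genes.

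Caloric restriction was set to match the weight of the operated mice, and body weights were not among the data used. Relative to obese mice, the clock output gene Dbp was higher and neutrophil genes were lower. Dbp, a clock output factor (chromosome 7, 45705088 to 45710203), rose from 40.5 ± 16.8 to 225 ± 75.1 CPM (log2 fold change 2.48 ± 0.37, adjusted p = 0.000401) in 8 of 8 mice. Hlf (1.67 ± 0.33) and Ciart (1.70 ± 0.38) rose too, while the clock activators Clock (-0.77 ± 0.17) and Npas2 (-2.41 ± 0.55) fell. The labels state neither the feeding times of the mice nor the time of day of collection. Of 12 neutrophil and monocyte genes 4 fell and none rose (6 fell adjusted over the list alone). They were Retnlg (-3.55 ± 0.59), the alarmin genes S100a9 (-3.02 ± 0.59) and S100a8 (-2.54 ± 0.49), and Csf3r, the receptor for granulocyte growth factor (-1.75 ± 0.34). The neutrophil list kept its camera call with an estimated correlation (adjusted p = 0.0435), and its mean per mouse was lower by 1.91 (exact permutation p = 0.000622, adjusted 0.028). Without the libraries with visceral fat transcripts, which left 5 obese mice, it was lower by 2.18 (exact permutation p = 0.00233), and the adjusted p was 0.0699. The erythrocyte list mean was 5.52 ± 0.60 log2 CPM in restricted and 6.22 ± 0.68 in obese mice. Whether blood content adds to the neutrophil change was not tested in this comparison. In all 96 genes were higher and 78 lower, but 58 and 90 with RLE factors, 32 and 67 with the length offset, 19 and 61 with 2 groups alone and 238 and 378 with DESeq2.

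Of 16 clock genes 3 rose and 2 fell (8 and 3 adjusted over the list alone), with an exact permutation p of 0.0314 for the list mean (adjusted 0.205). Single genes that fell were Cdkn1a, a cell cycle inhibitor gene, by 2.07 ± 0.30, the metallothionein gene Mt2 by 2.44 ± 0.55, and Pdk4, induced in fasting, by 1.66 ± 0.39. Mt2 lost its call without obese mouse 6 (log2 fold change -1.09, adjusted p = 0.173). Leaving out 1 mouse also ended the calls of Rsad2 and Oasl2 in 9 of 16 fits each (adjusted p up to 0.0716 and 0.0824), of Pdk4 in 7 (0.0702), and of Ciart and Npas2 in 4 each (0.0584 and 0.0759). Of 15 glucocorticoid and fasting response genes 3 fell (5 adjusted over the list alone), with an exact permutation p of 0.0087 (adjusted 0.131) and an adjusted p of 0.454 with an estimated correlation. Restricted mouse 4 had a mean of 4.54 log2 CPM in this list against 5.67 to 6.07 in the other restricted mice. Of 16 interferon response genes 3 fell (4 adjusted over the list alone), namely Ifi44 (-1.51 ± 0.31), Rsad2 (-1.03 ± 0.25) and Oasl2 (-0.98 ± 0.24), with an exact permutation p of 0.0598 and an adjusted p of 0.454 with an estimated correlation. Adamts4, a matrix protease gene, fell by 2.87 ± 0.45 and Slc4a1, of erythrocytes, by 3.04 ± 0.64. Lep (log2 fold change -0.70 ± 0.49, adjusted p = 0.517) and Adipoq (-0.78 ± 0.33, adjusted p = 0.25) did not pass, and the adipokine list mean had an exact permutation p of 0.097 and an adjusted p of 0.597 with an estimated correlation. The antibody gene Ighe was called with a log2 fold change of 11 ± 2.41 that rested on restricted mouse 4, without which it was 0.61 (adjusted p = 0.934). Antibody genes have near-identical copies, so their values are uncertain.

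Of 30 divisions of the same 16 mice, the real one counted, 3 gave 174 genes or more, with up to 909. The count was 0 within series 1, 263 within series 2, 5 without the muscle-rich libraries and 506 without the lymphoid-rich ones. Within those series the median log2 change of the neutrophil list was -1.42 and -2.96.

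Restriction was set to match the weight loss of operated mice, and the labels of both groups name high-fat food. Lep had a log2 fold change of -1.38 ± 0.50 between operated and restricted mice (adjusted p = 0.0919). Genes of neutrophils, monocytes and macrophages were higher in operated than in restricted mice. S100a9 (chromosome 3, 90692632 to 90695721) stood at 30.4 ± 17 CPM in operated and 2.72 ± 2.4 CPM in restricted mice (log2 fold change 3.49 ± 0.60, adjusted p = 0.00152, n = 8 each). Retnlg rose by 4.30 ± 0.61, S100a8 by 2.75 ± 0.49 and Csf3r by 2.23 ± 0.34, each in 8 of 8 operated mice beyond the restricted median. Of the 12 neutrophil and monocyte genes 8 rose and none fell (10 rose adjusted over the list alone). The call held with an estimated correlation (adjusted p = 0.0123), and the list mean per mouse had an exact permutation p of 0.000311 (adjusted 0.00699).

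Of 14 macrophage genes 10 rose (12 adjusted over the list alone), such as Adgre1 (2.26 ± 0.39), Clec10a (1.69 ± 0.28), Itgam (2.64 ± 0.49) and Fcgr1 (2.21 ± 0.43). The exact permutation p of the list mean was 0.00575 (adjusted 0.0647), and camera gave an adjusted p of 0.27 with an estimated correlation. Operated mouse 1, the only mouse of these groups with visceral fat transcripts, had a macrophage mean of 8.27 log2 CPM against 4.66 to 6.64 in the other operated mice, and the median log2 change of the list was 1.47 with and 0.92 without the libraries with such transcripts. The chemokine gene Ccl9 rose by 2.30 ± 0.40 and the complement receptor gene C5ar1 by 2.24 ± 0.46, while Ccl2 did not differ past the test (0.02 ± 0.64, adjusted p = 0.993). Of 17 cytokine and chemokine genes 3 rose, with an exact permutation p of 0.0113 (adjusted 0.102) and an adjusted p of 0.881 with an estimated correlation. Among 13 genes of lipid-associated macrophages 4 rose, including Trem2 (2.48 ± 0.74), Atp6v0d2 (2.95 ± 0.81) and Mmp12 (3.10 ± 0.88), while Itgax had 0.88 ± 0.49 (adjusted p = 0.308). Operated mice 1 and 8 held 84.1 and 86.2 CPM of Trem2, and 3 of 8 operated mice exceeded the restricted median. Without operated mouse 8 the log2 fold changes were 1.79 for Trem2, 1.72 for Atp6v0d2 and 1.28 for Mmp12 (adjusted p = 0.167, 0.199 and 0.368), and the calls were lost in 9, 5 and 4 of 16 fits without 1 mouse. The list mean had an exact permutation p of 0.395. Saa3, an acute phase gene, and Igha lost their calls without operated mouse 1, with log2 fold changes of 1.22 (adjusted p = 0.329) and 0.68 (adjusted p = 0.521). The mesothelial gene Upk3b was called with a log2 fold change of 7.14 ± 2.14 and had -1.13 (adjusted p = 0.777) without that mouse.

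Cholesterol synthesis genes and some single clock genes were lower. Dbp was lower by 1.49 ± 0.36, Hlf by 1.21 ± 0.33 and Ciart by 1.76 ± 0.38 in operated than in restricted mice. Npas2 was higher by 2.96 ± 0.56. These genes also differed between restricted and obese mice, with Npas2 lower and the others higher after restriction. The difference therefore need not lie in the operated mice. The clock list mean had an exact permutation p of 0.456. Of 18 cholesterol synthesis genes 5 fell and none rose (9 fell adjusted over the list alone), among them Msmo1 (-0.85 ± 0.14), Mvk (-1 ± 0.23) and Fdps (-0.97 ± 0.25), with an exact permutation p of 0.00559 (adjusted 0.0647) and an adjusted p of 0.594 with an estimated correlation. Mvk lost its call without restricted mouse 1 (-0.80, adjusted p = 0.0521), and Hlf and Fdps lost theirs in 5 and 4 of 16 fits without 1 mouse (adjusted p up to 0.0732 and 0.0856). The apolipoprotein genes Apoa2 (-6.02 ± 1.09) and Apoa1 (-5.84 ± 1.49) were lower. In all 367 genes were higher and 792 lower, and without lymphoid-rich libraries 1045 and 997. The count was 132 in a fit of the 2 groups alone and 161 without muscle-rich libraries, and within series 1 and 2 it was 0 and 434, while the median change of the neutrophil list was 3.47 and 2.75.

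**Figure D2:**
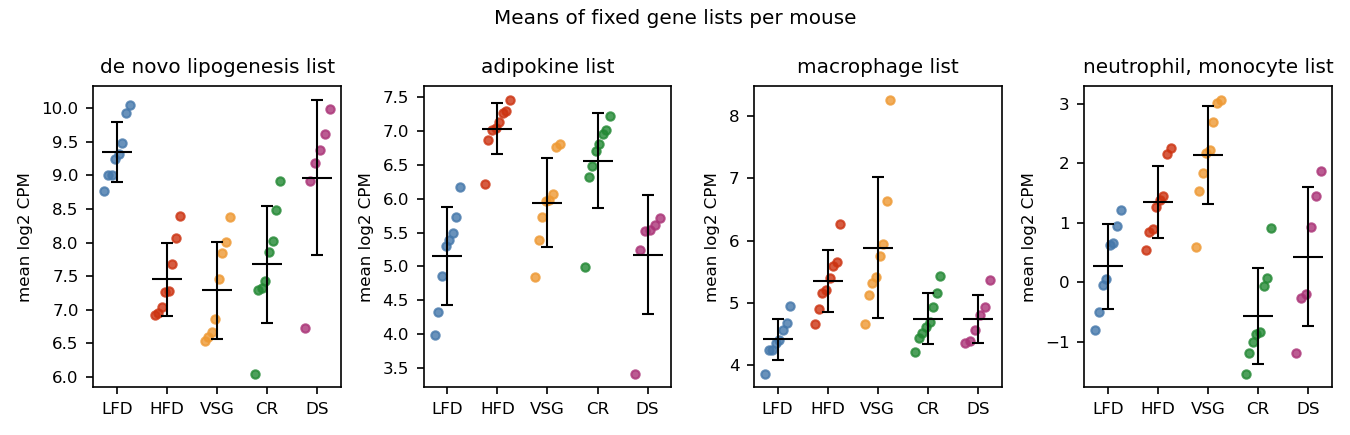
Mean log2 CPM of 4 fixed gene lists in each mouse (points), with the group mean (bar) and SD (whiskers). The neutrophil and monocyte mean was 2.14 ± 0.83 in operated and -0.56 ± 0.81 in restricted mice.

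Operated and switched mice had both lost weight, the first on high-fat and the second on low-fat food. Some lipogenic genes were lower and some macrophage genes higher in operated mice. Elovl6 stood at 21.3 ± 11.3 against 554 ± 406 CPM (log2 fold change -4.70 ± 0.56, adjusted p = 1.21e-05), Acly differed by -3.11 ± 0.47, Acaca by -2.54 ± 0.49, Fasn by -3.50 ± 0.74 and Slc2a5 by -6.02 ± 0.93. Of 16 lipogenic genes 6 fell and none rose (11 fell adjusted over the list alone), with an exact permutation p of 0.00999 for the list mean (adjusted 0.14). Of 14 macrophage genes 5 rose (11 adjusted over the list alone), among them Adgre1 (2.08 ± 0.43) and Clec10a (1.44 ± 0.30), with an exact permutation p of 0.0183 (adjusted 0.14). Operated mouse 1 had a macrophage mean of 8.27 log2 CPM against 4.66 to 6.64 in the other operated mice. Without it Adgre1 had 1.60 and Clec10a 1.02 (adjusted p = 0.0591 and 0.0574), and the count of genes was 36. Of 13 genes of lipid-associated macrophages 3 rose (5 rose and 1 fell adjusted over the list alone): Trem2 by 4.62 ± 0.93, Atp6v0d2 by 4.66 ± 1.00 and Mmp12 by 4.49 ± 1.06, with Itgax at 1.00 ± 0.54 (adjusted p = 0.558). Operated mice 1 and 8 held 84.1 and 86.2 CPM of Trem2 and the other operated mice 0.787 to 5.06. The list mean had an exact permutation p of 0.0999 (adjusted 0.321). The complement gene C4b rose by 1.62 ± 0.33, and the glycolytic genes Eno1 (-1.10 ± 0.23) and Gpi1 (-0.70 ± 0.15) fell.

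In all 40 genes were higher and 71 lower (51 and 43 without lymphoid-rich libraries), and camera called 14 lists, among them lipogenesis (adjusted p = 2.39e-17), macrophages (3.13e-11) and lipid-associated macrophages (0.0325), and none with an estimated correlation (adjusted p 0.116, 0.116 and 0.781). The count was 1 in a fit of the 2 groups alone, 3 without muscle-rich libraries and 12 within series 2. Without switched mouse 2 it was 22. Of 13 called genes named, 3 kept their call without each mouse in turn. Mmp12 lost it in 7 of 14 fits (2.67 without operated mouse 8, adjusted p = 0.18) and Atp6v0d2 in 5 (3.43 without that mouse, adjusted p = 0.0771). Gpi1 lost its call in 5, Adgre1, Clec10a and Eno1 in 4 each, Fasn in 3, Trem2 and C4b in 2 each and Acaca in 1 (adjusted p up to 0.104).

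The comparisons of operated and of restricted mice with lean mice showed what still differed in groups whose labels name no switch to low-fat food. In both groups lipogenic genes remained lower than in lean mice. Elovl6 differed by -5.14 ± 0.56 in operated and -4.23 ± 0.54 in restricted mice, Acly by -2.85 ± 0.45 in each, and Acaca by -2.67 ± 0.48 and -2.99 ± 0.48. In each group 8 of 16 lipogenic genes were lower and none higher (15 and 10 lower adjusted over the list alone), and the list mean had an exact permutation p of 0.000155 in operated and 0.000311 in restricted mice (adjusted 0.00699 and 0.014). The camera call held with an estimated correlation in operated mice (adjusted p = 0.0346) and not in restricted mice (adjusted p = 0.722). Brown adipocyte genes were lower in both, 5 of 10 in each, with Elovl3 at -4.47 ± 1.03 and -4.72 ± 1.04, and list means with exact permutation p values of 0.00155 and 0.000622. With an estimated correlation that list had an adjusted p of 0.0346 in operated and 0.722 in restricted mice.

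Operated mice differed from lean mice in 231 genes that were higher and 228 that were lower (333 and 83 without lymphoid-rich libraries, 134 and 265 with limma-voom). Of 14 macrophage genes 10 rose (14 adjusted over the list alone), such as Clec10a (1.88 ± 0.28), Csf1r (1.62 ± 0.26), Adgre1 (2.14 ± 0.39) and Mrc1 (1.58 ± 0.29), and of 12 neutrophil and monocyte genes 3 rose (9 adjusted over the list alone). The exact permutation p values were 0.000466 and 0.000932, and both calls held with an estimated correlation (adjusted p = 0.0346 and 0.0436). The median log2 change of the macrophage list was 1.73, and 1.14 without the libraries with visceral fat transcripts, here operated mouse 1. Trem2 rose by 3.98 ± 0.80, Atp6v0d2 by 4.24 ± 0.87, and Itgax had 1.53 ± 0.50 (adjusted p = 0.103). Operated mice 1 and 8 held 84.1 and 86.2 CPM of Trem2, the other operated mice 0.787 to 5.06 and lean mice 0.2 to 3.96. Its log2 fold change was 3.32 without mouse 1 and 3.29 without mouse 8 (adjusted p = 0.0166 and 0.0142). Each of these fits kept the other high mouse, so they do not show the difference without both. The mean of the lipid-associated list had an exact permutation p of 0.126. Of 12 complement genes 7 rose (9 adjusted over the list alone), with C4b at 1.77 ± 0.30 and Serping1 at 1.23 ± 0.25, an exact permutation p of 0.000466 and an adjusted p of 0.0689 with an estimated correlation. Operated mouse 1 had a complement mean of 7.55 log2 CPM against 5.11 to 6.16 in the other operated mice. Of 18 cholesterol synthesis genes 6 fell (10 adjusted over the list alone), including Nsdhl (-1.60 ± 0.31), Insig1 (-2 ± 0.41) and Fdps (-1.24 ± 0.25), with an exact permutation p of 0.00109 and an adjusted p of 0.0833 with an estimated correlation. Mest (3.03 ± 0.73) and Sfrp5 (3.10 ± 0.72) were higher, while Lep had 1.33 ± 0.50 (adjusted p = 0.185) and Adipoq -0.13 ± 0.33 (adjusted p = 0.976). The count of 459 was 133 without muscle-rich libraries, and 1 and 4 within series 1 and 2.

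Restricted mice differed from lean mice in 1276 genes that were higher and 676 that were lower. Adipokine genes stayed higher: Lep by 2.72 ± 0.52, Mest by 4.25 ± 0.77, Sfrp5 by 4.51 ± 0.77 and Npr3 by 3.02 ± 0.50, with 5 of 15 genes higher (6 adjusted over the list alone), an exact permutation p of 0.00249 (adjusted 0.0224) and an adjusted p of 0.723 with an estimated correlation. Adipoq had -0.06 ± 0.33 (adjusted p = 0.938). Retnlg (-2.32 ± 0.56), S100a9 (-2.03 ± 0.57) and Csf3r (-1.20 ± 0.33) were lower than in lean mice, 3 of 12 genes of that list (4 adjusted over the list alone), with an exact permutation p of 0.0476 (adjusted 0.195) and an adjusted p of 0.723 with an estimated correlation. Npas2 (-3.36 ± 0.57), Cdkn1a (-1.36 ± 0.30) and Sgk1, of the glucocorticoid response (-1.28 ± 0.31), were lower, and Dbp was higher by 1.22 ± 0.35, a call lost without restricted mouse 6 (adjusted p = 0.0576). Areg (-3.84 ± 0.89) and Krt19 (-2.43 ± 0.69) were lower, as was the epithelial list mean, by 1.53 on the log2 scale (exact permutation p = 0.00606, adjusted 0.0455, and an adjusted p of 0.872 with an estimated correlation). The count was 1 within series 1, 1630 within series 2 and 0 within series 3, and 834 without muscle-rich libraries.

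To ask how far each treated group had moved back toward lean mice, the 2393 genes that differed between obese and lean mice were followed. Obese and lean mice also differed in food, and among treated groups only the switched mice were labelled with the food of the lean mice. The counts below therefore do not separate the kind of weight loss from the food. Diet switch moved 1247 of them back past the test (52.1%; 815 that had been higher and 432 that had been lower), surgery 139 (5.81%) and restriction 63 (2.63%). The order of surgery and restriction turned round without lymphoid-rich libraries (0 and 126), muscle-rich ones (0 and 2) or those with visceral fat transcripts (4 and 29). None of the 2393 genes moved further from lean past the test. Still past the test against lean mice, in the same direction, were 308 (12.9%) after surgery, 1052 (44%) after restriction and 0 after the switch. Genes in neither count were not settled by the tests. Surgery and restriction against obesity called 158 and 174 genes in all, which bounds the numbers that could count as moved back. The direction alone was opposite for 99.8% of the genes after the switch, 92.5% after surgery and 82.1% after restriction. These comparisons share the obese libraries, and simulated unchanged groups gave 65.1%, 65.9% and 66%, with means of 0, 0 and 0.1 genes moved back. Independent lists of these sizes would overlap in 67 and 32.4 genes for the switch, 6.75 and 2.61 for surgery, and 5.16 and 4.48 for restriction (first those higher, then those lower in obesity). The covariance of the log2 fold changes across genes was -0.85, -0.60 and -0.37, against -0.29 in each simulation, a difference of -0.56, -0.31 and -0.08. Genes are not independent replicates, and the simulation draws each gene on its own, so it leaves out shared variation in tissue composition.

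When odd-numbered obese mice gave the obesity genes and even-numbered ones the reference for treatment, and then the reverse, the switch moved back 421 and 358 genes, surgery 39 and 0, and restriction 7 and 5. In the reverse split 5 genes moved further from lean after restriction, as many as moved back. Opposite directions made up 95.1% and 95.8%, 88.2% and 84.7%, and 75.4% and 56%.

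**Figure D3:**
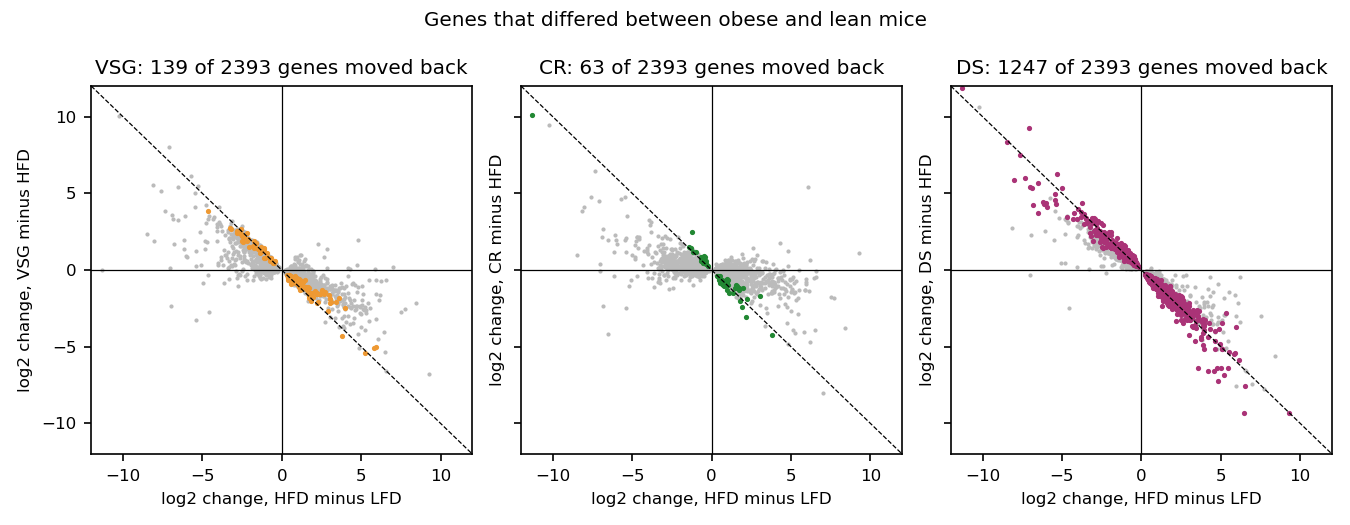
Each point is 1 of the 2393 genes, with its log2 change from lean to obese mice on the x axis and from obese to treated mice on the y axis. Coloured points moved back past the test, and the dashed line marks a full return to the lean level.

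Transcripts of neighbouring tissues varied between mice within every group. Lymphoid-rich libraries, with a B cell list mean above 2 log2 CPM, numbered 2 lean, 1 obese, 3 operated, 3 restricted and 2 switched mice. Muscle-rich ones numbered 2, 3, 1, 1 and 1 in the same order, and 3 obese and 1 operated mouse carried visceral fat transcripts. The mammary epithelial mean was 6.15 ± 0.72 log2 CPM in lean, 2.47 ± 3 in obese, 5.27 ± 2.37 in operated, 4.62 ± 1.03 in restricted and 5.6 ± 0.86 in switched mice.

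**Figure D4:**
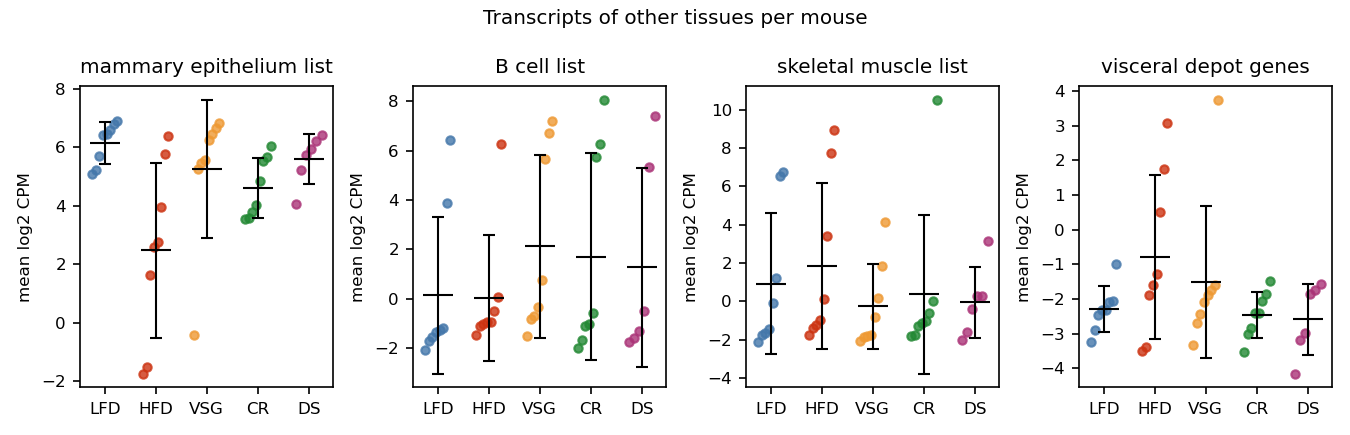
Mean log2 CPM of 4 gene lists of other tissues in each mouse (points), with the group mean (bar) and SD (whiskers). The B cell mean of the 11 lymphoid-rich libraries lay between 3.87 and 8.06, and that of the others at or below 0.78.

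**Figure D5:**
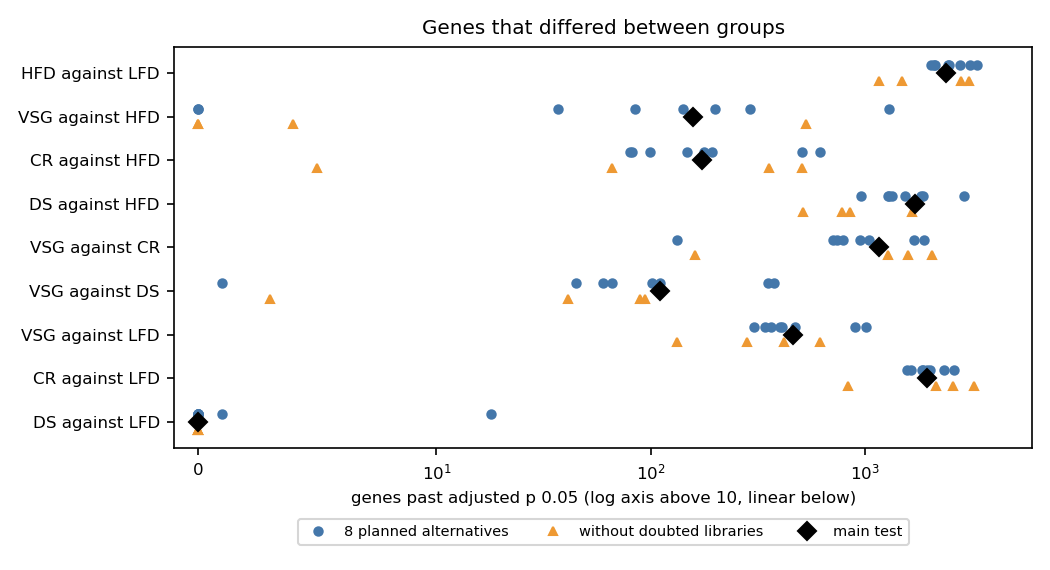
Genes past an adjusted p of 0.05 in 9 comparisons, on a log axis above 10, for the main test (diamonds), 8 alternative analyses (circles) and fits without libraries rich in other tissues or with few detected transcripts (triangles). Obese against lean mice kept more than 1000 genes throughout, while surgery against obesity ranged from 0 to 1285.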

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

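Of the tests weighed here, those of group, dilution, number series, lymphoid tissue in the myeloid pattern, single surgery libraries and blood were chosen after the result was seen, as were the lists of lymph node, visceral and subcutaneous genes.

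B and T cell transcripts were high in 11 libraries, spread over all groups (2 of 8 lean, 1 of 8 obese, 3 of 8 operated, 3 of 8 restricted and 2 of 6 switched mice). The inguinal mammary fat pad of the mouse holds a lymph node, and 6 genes of lymph node stroma stood higher in these libraries than in the others by a median of 5.35 on the log2 scale, among them Ccl21a by 9.48 and Cxcl13 by 5.13. Of these 6 genes 3, and of the 12 B cell genes 2, were also over 1 CPM in the median other library. The spread over groups gave a two-sided Fisher exact p of 0.855, which cannot exclude a smaller effect of diet or surgery. Lymph node tissue in the sampled piece is a candidate source of these transcripts, and an effect of group remains open.

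Mammary epithelial transcripts were lower in obese than in lean mice, by a median of -2.01 on the log2 scale. A larger share of adipocyte RNA would lower the other cell types alike, but 22 endothelial and fibroblast genes had a median log2 change of 0.614. This argues against a dilution of all other cell types alike. The adipocyte list mean was 9.96 ± 0.34 log2 CPM in lean and 9.90 ± 0.43 in obese mice. These values cannot test a dilution of the epithelium alone, because the genes compared belong to other cell types. With the number series as a term the epithelial median was -2.34, and within series 1 and 2 it was -4.22 and -1.02, which argues against the series as the whole cause but leaves open that it adds to the size. The 3 libraries with an epithelial mean under 0, of which 2 were obese and 1 operated, stood above the median of the others by 4.76 in visceral fat genes, so tissue of a visceral depot may account for part of the pattern; 1 of its 5 genes was over 1 CPM in other libraries. Tbx15, taken as a subcutaneous marker, stood at -0.40 and -0.47 log2 CPM in obese mice 1 and 3 and 1.44 in operated mouse 1. In every other library it was at least 2.81. The mean of the subcutaneous list, 1.16, 1.78 and 1.90 in these mice, lay within the range of the others (0.80 to 3.24). How much of these libraries came from another depot stays open. Without the 4 libraries with visceral transcripts the median was -1.37, and an effect of the diet stays open for that part.

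Neutrophil and monocyte transcripts were higher after surgery than after restriction, by a median of 2.88 on the log2 scale. Without lymphoid-rich libraries the median was 3.48, which argues against lymphoid tissue as the source. Leaving out any 1 operated mouse gave a median of at least 2.68, which argues against a single operated library. The mean of 6 erythrocyte genes differed by 0.419 ± 0.289 (SE; exact permutation p = 0.168), against 2.70 ± 0.41 for the neutrophil and monocyte list, which argues against more blood in the tissue as the whole cause. The list mean was 0.27 log2 CPM in lean, 1.35 in obese, 2.14 in operated, -0.56 in restricted and 0.43 in switched mice. Lower values after restriction are thus part of the difference, and no list mean passed between operated and obese mice (smallest adjusted exact permutation p = 0.0629). The time of day of collection and the make-up of the blood were not tested, so effects of surgery and of restriction are hypotheses among several.

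Other divisions of the same mice, 30 per comparison with the real one counted, tested how often chance gives as many genes. For obese against lean mice 1 of 30, the real one, reached 2393 genes, and the highest other gave 133. For operated against obese mice it was also 1 of 30 (158 genes, highest other 2), in the fit of 5 groups. The count was 0 with these 2 groups alone, with composition covariates and within series 1 and series 2, and the divisions set aside series and tissue make-up, so what carried the 158 genes stays open. Only the real division, 1 of 30, also reached its count for switched against obese (1707, highest other 664) and operated against restricted mice (1159, 776). The same held for operated against switched (111, 6), operated against lean (459, 115) and restricted against lean mice (1952, 1). With 30 divisions 1 of 30 is the smallest share possible, unadjusted over the 9 comparisons, so these counts speak against chance only to that extent. Series and tissue make-up were set aside here too. With 2 groups alone operated against switched mice gave 1 gene and operated against restricted mice 132. For restricted against obese mice 3 of 30 gave as many as the real 174, the highest 909, so chance cannot be excluded for that count. A division that calls several times the real count points to a structure of the samples, but which one stays open: the division with 909 genes put all 4 lymphoid-rich libraries on one side, and 3 others that did so gave 0, 0 and 149 genes. For switched against lean mice 30 of 30 gave as many as the real 0, with up to 9.

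Single mice stood apart from their group in 29 of 175 groups of values tested, by a gap to the nearest other mouse that was large relative to the range of the group. Chance gives about 1 in 20, or about 8.75. Values below are the list mean or gene in log2 CPM and the gap as a share of the range. Switched mouse 5 was lowest of its group in lipogenesis (6.73, share 0.67), adipokines (3.42, share 0.792), matrix genes (4.54, share 0.723), lipid-associated macrophages (4.29, share 0.712), hormone response (3.17, share 0.783), Lep (4.97, share 0.67) and Sparc (8.35, share 0.805), and highest in Igha (6.41, share 0.759). Restricted mouse 4 was lowest in adipokines (5, share 0.598), clock genes (4.28, share 0.776), glucocorticoid and fasting response (4.54, share 0.739) and Dbp (6.09, share 0.65), and highest in cytokines (2.54, share 0.586) and Ighg1 (13.69, share 0.546). Switched mouse 5 and restricted mouse 4 were both lymphoid-rich libraries and lowest of their groups in the adipocyte list, at 7.43 and 7.84.

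Operated mouse 1 was highest in complement (7.55, share 0.571), Igha (9.58, share 0.617) and Saa3 (9.48, share 0.707) and lowest in epithelial genes (-0.41, share 0.785). Lean mouse 1 was lowest in matrix genes (5.42, share 0.536), clock genes (4.33, share 0.567), Sparc (9.34, share 0.591) and Dbp (5.39, share 0.567). Lean mouse 3 was highest in Igha (5.70, share 0.527) and lean mouse 7 in skin keratinocyte genes (4.38, share 0.746). Obese mouse 1 was highest in oxidative phosphorylation (8.58, share 0.72) and obese mouse 2 in T cell genes (4.72, share 0.704). Restricted mouse 6 was highest in skeletal muscle (10.52, share 0.851) and brown adipocyte genes (3.42, share 0.607), and restricted mouse 2 in hormone response (4.64, share 0.576).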

How the results depend on the processing

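The fits without libraries rich in another tissue, without 2 switched mice and within a number series, and the permuted list means, with all mice or fewer, were chosen after the data had been seen. Unless stated, the cause of a change was not tested. Gene counts below are those that moved by more than 1.5 times.

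Obese against lean mice (2393 genes) gave 2036 to 3330 under 8 alternatives set before the data were examined, and 1840 to 2745 without any 1 mouse. It gave 1158 without muscle-rich and 1493 without visceral libraries, 18 and 346 within series 1 and 2, and 1151 also over 1 on the log2 scale; the last 5 have fewer mice or a stricter threshold by construction.

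Operated against obese mice (158) gave 84 without a filter, 37 with the series as a term, 0 with composition covariates, 0 with 2 groups alone, 290 with limma-voom, 1285 with DESeq2 and 86 over 1 on the log2 scale. It gave 0 without lymphoid-rich, 0 without muscle-rich and 4 without visceral libraries, and 0 within series 1 and 0 within series 2. Without 1 mouse it ran from 0 to 873: obese 1 27, 2 93, 3 2, 4 0, 5 873, 7 272 and 8 7, and operated 1 712, 2 670, 3 0, 5 75, 6 19, 7 20 and 8 0.

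Restricted against obese mice (174) gave 82 without a filter, 99 with the length offset, 508 with composition covariates, 80 with 2 groups alone, 616 with DESeq2 and 64 over 1. It gave 506, 5 and 66 without lymphoid-rich, muscle-rich and visceral libraries, and 0 and 263 within series 1 and 2. Without 1 mouse it ran from 80 to 294: obese 1 113, 3 80, 5 96, 6 98 and 8 114, and restricted 1 110, 2 294, 5 113, 7 112 and 8 105. More genes were higher than lower (96 and 78), as with the series (105 and 89), limma-voom (96 and 81) and covariates (367 and 141). Fewer were higher with RLE factors (58 and 90), without a filter (37 and 45), with the length offset (32 and 67), with 2 groups alone (19 and 61) and with DESeq2 (238 and 378).

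Switched against obese mice (1707) gave 956 with 2 groups alone, 2889 with DESeq2 and 788 over 1, 782 without muscle-rich, 853 without visceral libraries, 515 without switched mice 5 and 6, and 140 within series 2. Without 1 mouse it ran from 997 (switched 6) to 2012, with 1088 without obese 4.

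Operated against restricted mice (1159) gave 741 without a filter, 709 with the length offset, 132 with 2 groups alone, 1873 with DESeq2 and 432 over 1, 2042 and 161 without lymphoid-rich and muscle-rich libraries, and 0 and 434 within series 1 and 2. Without 1 mouse it ran from 360 to 1751: restricted 1 360, 4 1751, 6 414 and 7 406, and operated 3 576, 6 668, 7 704 and 8 415. Lower genes outnumbered higher ones (792 and 367), but without lymphoid-rich libraries 997 were lower and 1045 higher.

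Operated against switched mice (111) gave 66 without a filter, 60 with the series, 377 with covariates, 1 with 2 groups alone, 45 with limma-voom and 352 with DESeq2, 3 and 41 without muscle-rich and visceral libraries, and 12 within series 2. Without 1 mouse it ran from 22 to 212: operated 1 36, 5 212, 7 64 and 8 36, and switched 2 22, 3 34, 5 171 and 6 30. Without lymphoid-rich libraries 51 were higher and 43 lower, against 40 and 71.

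Operated against lean mice (459; 231 higher and 228 lower) had 333 higher and 83 lower without lymphoid-rich libraries, and 134 and 265 with limma-voom. The total was 304 without a filter, 1010 with covariates, 897 with DESeq2 and 287 over 1, 133 and 281 without muscle-rich and visceral libraries, and 1 and 4 within series 1 and 2. Without 1 mouse it ran from 236 to 686: operated 1 259, 6 287 and 7 278, and lean 2 291, 3 278, 4 286 and 8 236. Restricted against lean mice (1952) gave 864 over 1, 3217 and 834 without lymphoid-rich and muscle-rich libraries, 1 within series 1 and 0 within series 3, and 1443 to 2242 without 1 mouse. Switched against lean mice (0 with edgeR, 657 at an unadjusted p under 0.05) gave 18 with DESeq2, 0 with limma-voom, 1 with covariates and 0 to 0 without 1 mouse.

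Leaving out switched mice 5 and 6 also moved comparisons that hold no switched mice, through the filter and the spread that all groups share: 528 genes in operated against obese and 355 in restricted against obese mice.

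Permuted list means without visceral libraries, which leave 5 obese mice, lost the following calls (difference, adjusted p): matrix (0.70, 0.0649), epithelium (-2.05, 0.0649) and milk proteins (-0.98, 0.239) in obese against lean, neutrophils in restricted against obese (-2.18 against -1.91 with all mice, 0.0699), plasma cells in operated against lean (1.00, 0.065), and complement (-0.95, 0.0974), adipokines (-1.75, 0.0974) and unfolded protein response (-0.51, 0.111) in switched against obese mice.

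Camera called 147 list tests over the 9 comparisons, but 6 with an estimated correlation, and fry called 41 and permuted list means 36. Genes moved back after surgery (139) numbered 39 and 0 with obese mice split, 2213 by direction alone, and 0, 0, 430 and 4 without lymphoid-rich, muscle-rich, the 2 switched and visceral libraries. After restriction (63) they numbered 7 and 5, 1964, and 126, 2, 133 and 29. After the switch (1247) they numbered 421 and 358, 2389, and 576, 504 and 723 without muscle-rich, the 2 switched and visceral libraries.

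Directions reversed in these cases. Skeletal muscle in operated against obese mice had a median of 0.00377 with covariates and 0.32 without muscle-rich libraries, and Myh2 had 0.65 without them, as their removal implies. In operated against restricted mice Upk3b had -0.34 with limma-voom, -1.15 without visceral libraries and -1.13 to 7.43 without 1 mouse, Ccl2 had -0.0741 with limma-voom, -0.24 without visceral libraries and -0.25 to 0.23 without 1 mouse. Adipoq against lean mice had 0.10 (operated) and 0.21 (restricted) without lymphoid-rich libraries, and -0.20 to 0.0809 in restricted mice without 1 mouse, the last without restricted mouse 4. In switched against lean mice Lep had -0.16 and Elovl6 0.13 without lymphoid-rich libraries, and Lep -0.20 to 0.37 without 1 mouse. None of these 3 genes had passed the test there.

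Of the called genes named, the calls held under every alternative set before the data were examined for 22 of 31 in obese against lean, 0 of 13 in operated against obese, 9 of 18 in restricted against obese, 14 of 18 in switched against obese, 11 of 25 in operated against restricted, 1 of 13 in operated against switched, 13 of 17 in operated against lean and 13 of 17 in restricted against lean mice. In the same order 26, 0, 11, 14, 16, 3, 17 and 16 kept their call without each mouse in turn. Leaving out 1 mouse at a time cannot test calls that more than 1 mouse carried, such as Trem2 in operated against lean mice.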

Other observations

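The tests of list means given here were chosen after the data had been seen. Erythrocyte transcripts were higher in obese than in lean mice, with a list mean of 6.22 ± 0.679 against 5.33 ± 0.493 log2 CPM (exact permutation p = 0.0101, adjusted over 45 lists 0.0366), and camera with an estimated correlation gave an adjusted p of 0.623. Milk protein transcripts were lower, at -2.30 ± 1.58 against -0.49 ± 0.72 log2 CPM (exact permutation p = 0.0106, adjusted 0.0366), with an adjusted p of 0.614 with an estimated correlation. Obese mice 1 and 3, which carried visceral fat transcripts, had milk protein means of -4.24 and -4.21, and without the libraries with such transcripts the difference was -0.98 (exact permutation p = 0.0948). Neutrophil and monocyte transcripts were also higher in obese than in lean mice, by 1.08 (exact permutation p = 0.00606, adjusted 0.0273), with an adjusted p of 0.618 with an estimated correlation, and no gene of the list passed on its own. After the diet switch, genes of the unfolded protein response, which handles misfolded proteins in the endoplasmic reticulum, had a lower mean than in obese mice, by -0.52 on the log2 scale (exact permutation p = 0.00133, adjusted 0.03), with an adjusted p of 0.691 with an estimated correlation, and 1 of 14 genes fell. Switched mouse 5 had 5.12 against 5.60 to 6.01 in the other switched mice, and without it the difference was -0.41 (exact permutation p = 0.00466). Without the obese libraries with visceral fat transcripts it was -0.51 and the adjusted p 0.111, so that call was lost.

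Restricted mice had lower transcripts of fatty acid oxidation than lean mice (list mean 6.56 ± 0.60 against 7.26 ± 0.35 log2 CPM, exact permutation p = 0.0073, adjusted 0.047), with an adjusted p of 0.723 with an estimated correlation, and 3 of 15 genes fell. Restricted mouse 4, a lymphoid-rich library, had 5.30 against 6.32 to 7.14 in the other restricted mice, and without it the difference was -0.51 against -0.69 with all mice. Plasma cell transcripts were higher in operated than in lean mice, by 1.25 (exact permutation p = 0.0073, adjusted 0.0329), with an adjusted p of 0.48 with an estimated correlation. Operated mouse 1 had a plasma cell mean of 5.71 log2 CPM against 2.95 to 4.29 in the other operated mice, and without it the difference was 1.00 (exact permutation p = 0.0145, adjusted 0.065). Glucocorticoid and fasting response genes had a higher mean in operated than in restricted mice, by 0.67 (exact permutation p = 0.000155, the smallest these arrangements allow, adjusted 0.00699), with an adjusted p of 0.756 with an estimated correlation, and 2 of 15 rose. Restricted mouse 4 had 4.54 log2 CPM against 5.67 to 6.07 in the other restricted mice, and operated mice had 6.12 to 6.96. The group mean was 6.38 in operated, 6.39 in obese, 6.10 in lean, 6.23 in switched and 5.71 in restricted mice. Operated mice thus stood near obese ones, and restricted mice were lowest. Glycolysis genes were lower in operated than in lean mice, by -0.69 (exact permutation p = 0.000777, adjusted 0.00816), with an adjusted p of 0.0833 with an estimated correlation, and 4 of 15 fell.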
